A study of Mus musculus with 15 samples.

How the data were processed

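RNA was measured by sequencing in microglia sorted from mouse brain by flow cytometry. Per the labels, RNA was kept in RNAprotect, purified with RNeasy columns, amplified with the Ovation RNA-seq system, which makes cDNA from very small inputs, and built into libraries from low input. The deposited table holds TPM, transcript abundance scaled to a like total in each library, 1 column per library and 1 line per gene symbol; its columns carry the short names that the labels' description field gives the libraries, and each column was matched to 1 library by that name. Per the submitters' processing notes, the tools were FastQC 0.11.8, the transcript quantifier Salmon 1.0.0 and DESeq2, for which no version is given, with the mouse build GRCm38 (mm10). The deposited values are named as filtered. The filter used, the annotation behind the transcript index and the commands are not given in the sources used here.

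The table listed 13834 genes in 15 libraries, and no value in it equalled 0 (0 values). A gene with a value of 0 in any library, such as a gene absent from a whole group, could therefore not be tested or counted in a list. The symbols of 19 lines had been turned into dates and could not be read as genes. Of all symbols, 13744 (99.35%) were found in the GENCODE M21 annotation of GRCm38; of these 12770 (92.91%) were annotated as protein coding and 5 as lincRNA. Coordinates are from that annotation. Library totals ran from 956489 to 963145 TPM. A TPM value keeps no record of how many reads stood behind it, so the depth of each library is unknown, no counting interval was computed, and a low value cannot be given its sampling error. There were 0 pairs of identical libraries. Gene families with near-identical members, such as H2-Q6 and H2-Q7 or Ifi204 and Ifi207, can share reads, so their separate values are uncertain; whether reads were assigned by strand is not given in the sources used here.

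Libraries were grouped by the labels into AF-high (n = 5) and AF-low (n = 3), sorted from 18-month-old untreated mice for high or low autofluorescence, young (n = 3), from 3-month-old mice, and PLX5622 (n = 4), from 18-month-old mice given that compound. The titles call the libraries of a group biological replicates. Whether each came from 1 animal or from a pool is not given, nor whether same-numbered AF-high and AF-low libraries came from the same animal. Except with a replicate block, the tests take all libraries as independent, and the p-values measure the spread between these libraries. Sort markers, the autofluorescence gate of the young and PLX5622 groups, and the dose and schedule of the compound are not given in the sources used here. The groups, the tests, the gene lists, the alternatives and the rule for naming genes were chosen before the data were examined, except where they are said to have been chosen or added after values were seen.

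Values were taken as log2(TPM + 1), with a pseudocount of 1, for the 13175 genes with a TPM of at least 1 in at least 3 libraries. Fold changes on this scale understate the change of low genes. All 15 libraries entered 1 linear model with limma 3.58.1 in R 4.3.3 (lmFit, contrasts and eBayes with a trend of the variance on mean level; 11 residual and a median of 4.151 prior degrees of freedom). Tests were two-sided, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05 within each of the 6 comparisons. Every adjusted p given for a gene is limma's over the 13175 genes unless the words adjusted over the list alone stand beside it. Count-based tests were planned only in case the table held counts and were not run. Tables were read with jsonlite 2.0.0, and figures were drawn in Python 3.11.15 with matplotlib 3.10.9.

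Of 37 gene lists written from general knowledge of microglia and of other cells a brain sort can hold, 32 had at least 5 measured members and were tested with limma's camera on the same matrix and model, which compares a list with all other genes. The correlation between genes was preset at 0.01, with Benjamini-Hochberg adjustment over the 32 lists of a comparison. The alternatives were a correlation estimated from each list's residuals and fry, which asks whether a list's genes move one way on balance without comparing them with other genes. The other 5 lists had too few measured members for a test: erythroid cells (2 of 11), neutrophils (4 of 18), nuclear-retained and structural RNAs (0 of 16), oligodendrocyte precursors (1 of 12), and pericytes and smooth muscle (3 of 18).

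Genes are named by a fixed rule. For AF-high against AF-low, AF-high against young and PLX5622 against AF-high, the 8 largest rises and the 8 largest falls are named among genes with adjusted p under 0.05, a mean of at least 5 TPM in the higher group and no overlap between the groups; for the other 3 comparisons the numbers are 4 and 4. Numbered gene models (Gm with a digit, Rik), pseudogenes, mitochondrial and ribosomal protein genes are passed over in that part. Where none passes in a direction, the 3 with the smallest unadjusted p and a mean of at least 5 TPM are named as not past the test. Up to 4 members of each described list, those with the smallest p at a mean of at least 5 TPM, and Cd68, Apoe, P2ry12 and Tmem119 are named as well. The rule named 150 distinct genes; any other gene is said to have been chosen after its values were seen.

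Correlations of fold changes between comparisons were set against 100 simulations of groups with no effect that share the same libraries, and were recomputed with the shared libraries split where each part kept at least 2. Measures of whole libraries were compared in 6 exact permutation tests, two-sided, with Benjamini-Hochberg adjustment over those 6. The share of satellite-like transcripts is the sum of 10 numbered gene models, chosen after their values were seen. Alternatives fixed in advance were pseudocounts of 0.1 and 5, no filter, a filter at 5 TPM, median-of-ratios scaling, quantile normalization, scaling that leaves aside the 50 highest genes, a fit of only the groups compared, a replicate block, array weights and leaving out each library in turn. Leaving aside 3 outlying old libraries (AF-high 2, AF-high 3 and AF-low 1), leaving aside young 1 and 2, and weights by group were added after seeing the data.

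The gene test was checked on simulated data of 13175 genes with 67, 67 and 66 genes changed by 1.5, 2 and 4 fold. With a spread equal in all groups, 2-fold and 4-fold changes were recovered in 35.8% and 92.4% of genes for AF-high against AF-low, 47.8% and 89.4% for AF-high against young, 38.8% and 92.4% for AF-low against young, 44.8% and 92.4% for PLX5622 against AF-high, 43.3% and 92.4% for PLX5622 against AF-low, and 38.8% and 92.4% for PLX5622 against young. At 1.5 fold the shares were 4.5%, 6%, 0%, 11.9%, 9% and 4.5% in the same order. False calls at that spread were 6 of 94, 1 of 96, 10 of 97, 6 of 105, 6 of 102 and 3 of 93. The first simulation used the SD measured per gene and group and gave false calls of 94 of 200, 9 of 106, 33 of 119, 16 of 111, 44 of 142 and 3 of 93; the equal spread and a spread scaled by group were added after those were seen. The spread scaled by group gave 45 of 146, 1 of 94, 7 of 87, 7 of 105, 9 of 103 and 0 of 86. Under both unequal spreads the comparison of the gates had the most false calls; what set the false calls of the other comparisons was not separated.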

Results

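The series concerns a phenotype that microglia, the resident macrophages of the brain, acquire with age, and whether it can be reversed. RNA was sequenced from sorted mouse microglia in 15 libraries of 4 groups. The old, 18-month-old mice gave microglia of high autofluorescence (AF-high, n = 5) and of low autofluorescence (AF-low, n = 3). A further group (PLX5622, n = 4) came from mice of that age given PLX5622, an inhibitor of the CSF1 receptor used to deplete microglia. The young group (n = 3) came from 3-month-old mice. Autofluorescence in old microglia is commonly ascribed to undegraded material stored in lysosomes. Levels are means ± SD in TPM, transcript abundance scaled to a like total in each library, and changes are differences of log2(TPM + 1) ± SE from limma over 13175 genes. Library totals lay between 956489 and 963145 TPM; the depth in reads is unknown.

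The AF-high and AF-low libraries scattered more than the others. A library deviated from its group mean by 0.529 ± 0.0691 log2 units (root mean square over genes, SD, n = 8) in these gated old groups and by 0.299 ± 0.0136 (n = 7) in the young and PLX5622 groups (exact permutation test, two-sided, p = 0.000311, adjusted p = 0.00187 over 6 library tests). Libraries of a group share the mean they deviate from, so their deviations are not independent and this p-value may be too small. Satellite-like transcripts made up 10% ± 2.81 of TPM in PLX5622 libraries and 0.858% ± 0.823 in the 8 gated old libraries (exact permutation test, adjusted p = 0.00606). The gene models summed for this measure were chosen after their values were seen, which its p-values do not take into account. The young libraries had 4.58% ± 5.69, with 11.1% in young 1 and 0.634% in young 2 (exact permutation test against PLX5622, adjusted p = 0.222). What set the share of satellite-like transcripts was not tested, so its difference is not ascribed to the compound. Mitochondrially encoded transcripts took 4.12% ± 2.33 of TPM in AF-high, 2.15% ± 0.0848 in young and 2% ± 0.337 in PLX5622 libraries. The AF-high mean joins 5.376% and 7.657% in AF-high 2 and 3 with 2.372% to 2.698% in the other 3. Neither contrast passed its exact permutation test (adjusted p = 0.188 for both). Ribosomal protein transcripts took 5.139% ± 1.248 in AF-high and 4.17% ± 0.48 in PLX5622 libraries (exact permutation test, adjusted p = 0.222).

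**Figure D1:**
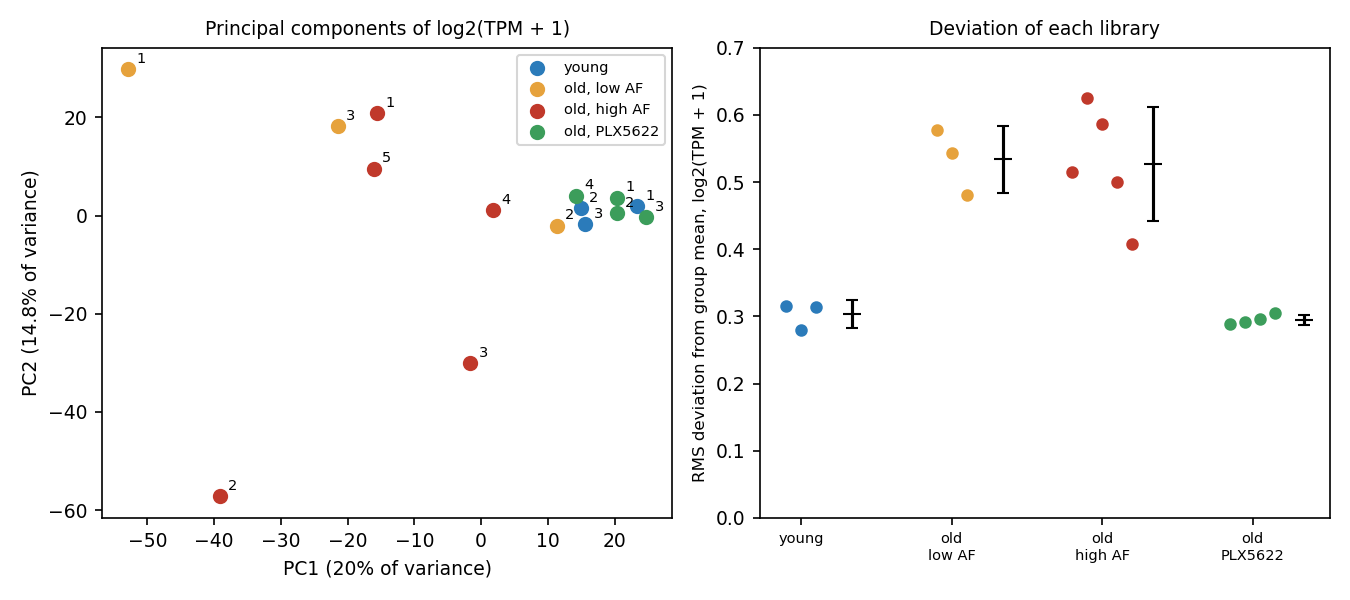
Left, the 15 libraries on the first 2 principal components of log2(TPM + 1), which hold 20% and 14.8% of the variance. Right, each library's root mean square deviation from its group mean in log2 units, with mean ± SD per group: the 8 AF-high and AF-low libraries average 0.529 and the 7 others 0.299.

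The comparison of AF-high with AF-low microglia asked what goes with autofluorescence at 1 age. Homeostatic microglial genes rose as a list in AF-high cells, with 20 of 28 members above 0 and a median log2 change of 0.23 against -0.04 for all genes (camera adjusted p = 6.22e-05; adjusted p = 0.889 with an estimated correlation). Among them were Adgrg1, an adhesion receptor, at 342.9 ± 153.5 TPM in AF-high (n = 5) and 178.6 ± 25.98 in AF-low (n = 3). Siglech, a microglial lectin, was at 981.5 ± 75.9 and 761.3 ± 132. Lysosomal genes rose as a list, 39 of 51 being positive (median 0.14, adjusted p = 0.000721; adjusted p = 0.889 with an estimated correlation). Ctsd, a lysosomal protease, was at 2971 ± 247.3 and 2358 ± 527.3 TPM and Ctso at 41.18 ± 7.16 and 28.9 ± 4.021. The lysosomal list was called in this 1 comparison only, and neither it nor the homeostatic list was called between AF-high and young. The lysosomal list mean in log2(TPM + 1) was 6.694 to 6.906 in AF-high, 6.696 to 6.743 in AF-low and 6.693 to 6.86 in young libraries. A rise in AF-high over young cells is therefore not shown for these 2 lists. All 13 measured mitochondrially encoded genes were positive (median 0.59, adjusted p = 6.22e-05; adjusted p = 0.96 with an estimated correlation). Of these mt-Co1, a subunit of cytochrome oxidase, was at 11320 ± 4438 and 7077 ± 127 TPM. AF-high 2 and 3 carried 5.376% and 7.657% mitochondrial transcripts.

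Markers of border-associated macrophages, which line vessels and meninges, fell as a list in AF-high cells (16 of 20 negative, median -0.22, adjusted p = 0.0309; adjusted p = 0.889 with an estimated correlation). F13a1, a coagulation factor subunit, was at 6.839 ± 1.138 TPM in AF-high and 13.61 ± 4.716 in AF-low. The scavenger receptor Cd163 was at 3.465 ± 0.8008 and 6.549 ± 0.5667 TPM, and the mannose receptor Mrc1 at 23.27 ± 1.605 and 32.2 ± 3.602. Immediate early and heat shock genes, which respond within minutes to handling and stress, also fell (26 of 29 negative, median -0.21, adjusted p = 0.0319; adjusted p = 0.96 with an estimated correlation). Rgs1, a regulator of G-protein signalling, was at 255.9 ± 99.66 and 364 ± 38.87 TPM. No member of these 5 lists passed over all genes (0) or adjusted over the list alone (0). The border-associated list lost its call without AF-high 3, 4 or 5 or AF-low 1 or 3 (adjusted p = 0.151, 0.0516, 0.0542, 0.0994 and 0.168). The immediate early list lost it without AF-high 1, AF-high 5 or AF-low 2 (0.224, 0.314 and 0.616), and the homeostatic list without AF-low 1 (0.0994). With AF-high 2, AF-high 3 and AF-low 1 left aside together, a choice made after seeing the data, the homeostatic, mitochondrial and border-associated lists had adjusted p = 0.412, 0.858 and 0.479. With weights by group, also chosen after seeing the data, the immediate early list had 0.0642.

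No single gene passed the test between the gates (limma, 0 of 13175, smallest adjusted p = 0.441). There were 1082 genes at an unadjusted p under 0.05, where 659 would be reached if all p-values were uniform. Other splits of these libraries into groups of the same sizes gave a median of 1217 such genes, so 1082 was no excess. The groups did not overlap for 363 genes (2.76%, against 3.57% by chance). Nearest to the threshold were Cd74, the invariant chain of MHC class II, at 79.13 ± 7.772 TPM in AF-high and 135.9 ± 13.9 in AF-low (log2 -0.77 ± 0.14, adjusted p = 0.441). The actin regulator Diaph1 was at 21.95 ± 5.977 and 45.86 ± 1.955 TPM (-1.07 ± 0.21, 0.441) and Hspa1l at 2.66 ± 0.545 and 7.124 ± 0.526 (-1.16 ± 0.24, 0.441). On the other side stood Smim1 at 11.49 ± 4.36 and 4.412 ± 0.35 TPM (1.14 ± 0.24, 0.441). Pvrig, an inhibitory receptor, was at 6.806 ± 2.179 and 1.869 ± 1.143 (1.48 ± 0.31, 0.444) and Chd1l at 9.581 ± 3.212 and 3.806 ± 1.633 (1.14 ± 0.26, 0.444). The phagolysosomal marker Cd68 was at 1287 ± 317.8 and 1124 ± 130 TPM (adjusted p = 0.81). Apoe, P2ry12 and Tmem119 had adjusted p = 0.958, 0.666 and 0.714. Without AF-high 2 or AF-low 3 the count was 1.

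AF-high microglia were then compared with young microglia, whose autofluorescence gate is not given in the sources used here, so that age and gate are not separated. Inflammatory cytokine and NF-kappaB genes rose as a list in AF-high cells (32 of 39 positive, median log2 change 0.42 against -0.08 for all genes, camera adjusted p = 7.77e-12; adjusted p = 0.0655 with an estimated correlation). So did genes of disease-associated microglia (24 of 30, median 0.26, 3.01e-10), type I interferon response genes (37 of 51, median 0.21, 2.39e-06) and complement genes (14 of 17, median 0.16, 0.000171). With an estimated correlation each of these 3 lists also had adjusted p = 0.0655. Spp1, which encodes osteopontin, was at 13.88 ± 8.634 TPM in AF-high (n = 5) and 1.558 ± 0.7083 in young (n = 3) (log2 2.41 ± 0.41, adjusted p = 0.0582). The growth factor Csf1 was at 289.8 ± 68.63 and 139 ± 35.21 TPM (1.05 ± 0.23, 0.121), and the integrin Itgax at 8.466 ± 1.864 and 2.901 ± 0.06472 (1.26 ± 0.29, 0.123). The costimulatory ligand Cd80 was at 92.06 ± 18.62 and 49.3 ± 5.237 TPM and the chemokine Cxcl16 at 141.5 ± 48.19 and 65.52 ± 1.867. The DNA sensor Ifi207 was at 34.46 ± 7.172 and 15.39 ± 0.9257, and complement C4b at 10.33 ± 5.077 and 3.897 ± 1.113. No member passed over all genes (0). When adjusted over the list alone, 14 inflammatory genes were higher and 1 lower, and 9 disease-associated, 3 interferon and 2 complement genes were higher.

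Ribosomal protein genes (43 of 54 positive, median 0.22, adjusted p = 1.54e-09) and mitochondrially encoded genes (13 of 13, median 0.73, 8.55e-09) rose as lists in AF-high cells (adjusted p = 0.44 and 0.231 with an estimated correlation). Rpl22 was at 473.9 ± 90.54 against 302.4 ± 31.34 TPM in young and mt-Nd1 at 6679 and 7912 TPM in AF-high 2 and 3, 2480 to 2660 in the other AF-high libraries and 2027 ± 144.7 in young. With AF-high 2, AF-high 3 and AF-low 1 left aside the mitochondrial list had adjusted p = 0.0177. Border-associated macrophage markers rose as well (16 of 20, median 0.32, 0.000336; adjusted p = 0.159 with an estimated correlation). Pf4, a platelet chemokine gene also used by these macrophages, was at 38.35 ± 18.57 and 19.83 ± 7.393 TPM. Oxidative stress genes (20 of 35 positive, median 0.09, 0.0294; adjusted p = 0.231 with an estimated correlation) included Nfe2l2, a regulator of antioxidant genes, at 382 ± 73.3 and 270.9 ± 27.93 TPM. The MHC list was called higher (0.0328; adjusted p = 0.206 with an estimated correlation) although 13 members were positive and 13 negative, its median was -0.02 and its mean 0. B2m, the light chain of MHC class I, was at 7997 ± 609.9 and 5894 ± 149.1 TPM and H2-Q7 at 222.4 ± 62.05 and 93.91 ± 9.715. Immediate early and heat shock genes fell (24 of 29 negative, median -0.26, 0.0134; adjusted p = 0.604 with an estimated correlation). The chaperone Hspa8 was at 2066 ± 374.3 TPM in AF-high and 4926 ± 1423 in young. No member of these 6 lists passed over all genes (0). Adjusted over the list alone, 3 MHC genes were higher and Hspa8 was the 1 lower immediate early gene. The ribosomal, mitochondrial, border-associated and oxidative lists had 0 by that count. The MHC call was lost without AF-high 1, AF-high 4 or young 1 (adjusted p = 0.113, 0.0899 and 0.0668) and the oxidative call without AF-high 1, AF-high 5 or young 1 (0.0843, 0.0949 and 0.0961). Under quantile normalization, with only both groups and with young 1 and 2 left aside the MHC list had adjusted p = 0.185, 0.0644 and 0.234 and the oxidative list 0.224, 0.0605 and 0.324, and with a filter at 5 TPM the oxidative list had 0.0968. The immediate early call was lost without AF-high 1, AF-high 5, young 2 or young 3 (0.0841, 0.103, 0.0672 and 0.424).

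Markers of other brain cells fell as lists from young to AF-high: astrocytes (8 of 10 negative, median -0.52, adjusted p = 0.000336; adjusted p = 0.2 with an estimated correlation) and oligodendrocytes (7 of 10, -0.65, 0.002; adjusted p = 0.206 with an estimated correlation). The same held for endothelial cells (9 of 11, -0.79, 0.0169; adjusted p = 0.354 with an estimated correlation) and choroid plexus and ependyma (5 of 6, -2.07, 0.002; adjusted p = 0.206 with an estimated correlation). Of their genes 4, 6, 3 and 4 were lower adjusted over the list alone, against 0 over all genes. The high levels lay in young 1 and 2. Ttr, the transthyretin gene of the choroid plexus, was at 7770, 5084 and 175.7 TPM in young 1, 2 and 3 and at 184.3 ± 136.5 in AF-high. Clu, an abundant astrocyte gene, was at 77.8, 66.3 and 3.31 TPM and at 2.128 ± 2.203. The glycolytic enzyme Aldoc was at 0.9594 ± 0.5468 TPM in AF-high and 16.54 ± 11.12 in young, and Enpp2 at 16.76 ± 8.356 and 521.7 ± 452.9. With young 1 and 2 left aside, a choice made after seeing the data, these 4 lists were not called (adjusted p = 0.498, 0.727, 0.727 and 0.727; the 1 remaining young library is then taken to vary like the other groups) and the endothelial and choroid plexus lists changed direction. By single libraries the endothelial call was lost without AF-high 1, AF-high 3 or young 2 (0.0501, 0.084 and 0.198). With a filter at 5 TPM the astrocyte, oligodendrocyte and endothelial lists had adjusted p = 0.37, 0.113 and 0.379. The endothelial list had 0.103 with array weights, 0.0544 with weights by group and 0.111 without the 3 outlying old libraries.

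Gene by gene, none passed between AF-high and young (limma, 0 of 13175, smallest adjusted p = 0.0582), with 1446 genes at an unadjusted p under 0.05. The groups did not overlap for 1025 genes (7.78%, against 3.57% by chance). Beside Spp1, the genes with the smallest p were Ildr2 at 18.5 ± 3.602 TPM in AF-high and 7.664 ± 0.1791 in young (log2 1.15 ± 0.17, adjusted p = 0.0582) and H2-Q7 (1.2 ± 0.20, 0.0582). On the lower side these were Fam107a at 0.2419 ± 0.2411 and 6.791 ± 4.629 (-2.40 ± 0.38, 0.0582), Aldoc (-2.88 ± 0.47, 0.0582) and Calml4 at 1.743 ± 1.406 and 18.48 ± 9.965 (-2.79 ± 0.48, 0.0582). Young 1 and 2 stood apart for these 3, with Fam107a at 8.933, 9.959 and 1.479 TPM in young 1, 2 and 3, Aldoc at 23.07, 22.85 and 3.701 and Calml4 at 27.09, 20.78 and 7.561. Cd68 was at 1287 ± 317.8 and 899.3 ± 45.82 TPM (0.49 ± 0.17, 0.296). Apoe, P2ry12 and Tmem119 had adjusted p = 0.831, 0.742 and 0.998. Leaving out a library gave 9 genes without AF-high 1, 19 without AF-high 4, 4 without AF-low 2 and 60 without young 3.

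For AF-low against young microglia, which differ in age and, the gate of the young cells not being given in the sources used here, possibly in gate, 6 genes rose and 0 fell (limma, adjusted p under 0.05 of 13175). The B-cell chemokine gene Cxcl13 (chromosome 5, 95956951 to 95961068, GRCm38) was at 12.33 ± 3.01 TPM in AF-low (n = 3) and 0.5156 ± 0.5567 in young (n = 3) (log2 3.17 ± 0.52, adjusted p = 0.0462). The membrane protein gene Emp3 rose from 66.84 ± 4.702 to 289 ± 123.3 TPM (1.99 ± 0.32, 0.0441). Ifi207 rose from 15.39 ± 0.9257 to 48.51 ± 11.95 (1.57 ± 0.23, 0.0374) and Diaph1 (chromosome 18, 37843601 to 37935476) from 15.92 ± 2.188 to 45.86 ± 1.955 (1.48 ± 0.23, 0.0441). The other 2, named here after their values were seen, were the inhibitory receptor Lilrb4a, from 103.2 ± 13.65 to 255.6 ± 68.93 TPM (1.27 ± 0.19, 0.0374), and the prostaglandin receptor Ptger4, from 15.87 ± 2.73 to 37.36 ± 5.441 (1.19 ± 0.20, 0.0462). Nearest on the lower side, not past the test, were Fam107a at 0.2704 ± 0.15 TPM in AF-low and 6.791 ± 4.629 in young (-2.35 ± 0.42, 0.056), with 8.933, 9.959 and 1.479 TPM in young 1, 2 and 3. Fnbp1l was at 13.23 ± 1.662 and 36.35 ± 15.57 (-1.31 ± 0.24, 0.056) and Mospd1 at 3.48 ± 0.583 and 11.25 ± 2.407 (-1.44 ± 0.27, 0.0637).

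Inflammatory genes rose as a list in AF-low cells (33 of 39 positive, median 0.51 against -0.04 for all genes, camera adjusted p = 2.88e-10; adjusted p = 0.121 with an estimated correlation). The chemokine Cxcl2 was at 89.32 ± 21.32 TPM against 29.69 ± 4.299 in young and the interleukin-1 antagonist Il1rn at 16.84 ± 11.81 against 1.887 ± 1.205. Border-associated macrophage markers rose (18 of 20, median 0.71, 9.45e-07; adjusted p = 0.121 with an estimated correlation). Mrc1 was at 32.2 ± 3.602 against 17.89 ± 0.9252 TPM, Pf4 at 66.45 ± 16.49 against 19.83 ± 7.393 and Dab2 at 179.5 ± 96.54 against 63.18 ± 7.854. Type I interferon (37 of 51, median 0.25, 5.28e-05) and MHC genes (18 of 26, median 0.20, 0.00521) rose, both with adjusted p = 0.121 with an estimated correlation. Cd74 was at 135.9 ± 13.9 against 72.68 ± 7.26 TPM. Disease-associated (21 of 30, median 0.33, 9.69e-05), complement (10 of 17, median 0.16, 0.00835) and ribosomal protein genes (46 of 54, median 0.25, 6.28e-06) rose too (adjusted p = 0.168, 0.182 and 0.653 with an estimated correlation). Itgax was at 13.66 ± 6.548 against 2.901 ± 0.06472 TPM. Homeostatic genes fell (21 of 28 negative, median -0.22, 0.00186; adjusted p = 0.456 with an estimated correlation). The microglial Fc receptor-like gene Fcrls was at 616.5 ± 112.2 against 916.5 ± 52.85 TPM and the fructose transporter Slc2a5 at 79.81 ± 21.11 against 143 ± 16.85. The genes higher when adjusted over the list alone were 8 inflammatory, 8 border-associated, 3 interferon, 3 MHC, 5 disease-associated and 2 complement genes. By the same count 1 border-associated and 3 homeostatic genes were lower and 0 ribosomal genes passed. Over all genes only the interferon list held a called gene (1, Ifi207). The homeostatic call was lost without AF-low 1 (adjusted p = 0.0969) or the 3 outlying old libraries (0.056), the complement call without AF-low 3 (0.101) and the MHC call without AF-low 2 (0.0802).

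Markers of astrocytes (7 of 10 negative, median -0.56, adjusted p = 0.00158; adjusted p = 0.218 with an estimated correlation) and oligodendrocytes (9 of 10, -0.72, 5.28e-05; adjusted p = 0.121 with an estimated correlation) fell from young to AF-low. Those of endothelial cells (9 of 11, -0.46, 0.0175; adjusted p = 0.456 with an estimated correlation) and choroid plexus (5 of 6, -1.77, 0.00929; adjusted p = 0.295 with an estimated correlation) fell too. Members lower when adjusted over the list alone were 4, 6, 3 and 4, against 0 over all genes. Slc1a2, an astrocyte glutamate transporter, was at 34, 64.1 and 4.27 TPM in young 1, 2 and 3 and at 1.096 ± 0.1915 in AF-low. Without young 1 and 2 none of the 4 was called (adjusted p = 0.403, 0.146, 1 and 0.553) and the endothelial and choroid plexus lists changed direction. The endothelial call was lost without AF-low 2 or young 2 (0.328 and 0.199) and the choroid plexus call without AF-low 2 or young 1 (0.0571 and 0.086). With only both groups, array weights and weights by group the endothelial list had adjusted p = 0.0986, 0.105 and 0.0836 and the choroid plexus list 0.0613, 0.141 and 0.0858. With a filter at 5 TPM the astrocyte and endothelial lists had 0.146 and 0.257.

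In all, 1551 genes had an unadjusted p under 0.05 between AF-low and young, and the groups did not overlap for 2548 genes (19.3%, against 10% by chance). Cd68 was at 1124 ± 130 and 899.3 ± 45.82 TPM (adjusted p = 0.522). P2ry12, a purinergic receptor of homeostatic microglia, was at 1599 ± 369 and 2446 ± 240 (0.325), and Apoe and Tmem119 had adjusted p = 0.758 and 0.626. The count of 6 was 0 without AF-high 4, AF-high 5, AF-low 1, young 1, young 2 or PLX5622 library 2, 3 or 4. It was 2 without AF-low 3, 10 and 12 without AF-high 1 and 2, 52 without young 3 and 182 without AF-low 2. Of Cxcl13, Emp3, Ifi207 and Diaph1, 0 were called in all 15 fits that left 1 library out. All 4 calls were lost without AF-high 4 or 5, AF-low 1 or 3, young 1 or 2 or PLX5622 library 2, 3 or 4, and those of Cxcl13 and Emp3 also without PLX5622 library 1 (adjusted p from 0.0545 to 0.234). Lilrb4a and Ptger4 lost theirs in 9 and 11 of these fits (highest adjusted p = 0.194 for both), Ptger4 also without young 3 (0.0527).

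PLX5622 against AF-high microglia asked how cells of treated old mice differ from strongly autofluorescent cells of untreated mice. The mannose receptor Mrc1 (chromosome 2, 14229392 to 14332057) fell from 23.27 ± 1.605 TPM in AF-high (n = 5) to 8.752 ± 2.328 in PLX5622 (n = 4) (log2 -1.34 ± 0.16, limma adjusted p = 0.00603). The homeostatic gene Crybb1 (chromosome 5, 112255815 to 112269585) fell from 253.4 ± 30.59 to 104 ± 18.99 (-1.29 ± 0.19, 0.0215). The lectin Cd209a fell from 7.85 ± 2.65 to 1.415 ± 0.8645 TPM (-1.91 ± 0.34, 0.0289). Ripk3, a kinase of necroptosis, fell from 15.69 ± 4.08 to 3.571 ± 0.913 (-1.85 ± 0.33, 0.0289), and the adhesion receptor Adgre5 from 20.89 ± 5.106 to 6.054 ± 3.135 (-1.68 ± 0.28, 0.0231). The other largest falls were in Ece1 (-1.76 ± 0.36, 0.0426), Mospd3 (-1.55 ± 0.33, 0.0495) and Atn1 (-1.26 ± 0.21, 0.0231). Cxcl13 rose from 3.724 ± 2.704 to 21.12 ± 5.345 TPM (2.45 ± 0.43, 0.0266). The lectin Lgals3 rose from 2.092 ± 1.357 to 8.838 ± 2.762 (1.77 ± 0.34, 0.0362) and the interferon-induced gene Samd9l from 3.227 ± 0.4311 to 9.82 ± 0.9434 (1.36 ± 0.24, 0.0266). The other largest rises were in Dnajc28 (1.37 ± 0.26, 0.0362), Rai14 (1.10 ± 0.23, 0.0495), Ndufv3 (1.05 ± 0.21, 0.0392), Trim44 (1.00 ± 0.20, 0.0369) and Lysmd4 (0.93 ± 0.18, 0.0369).

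**Figure D2:**
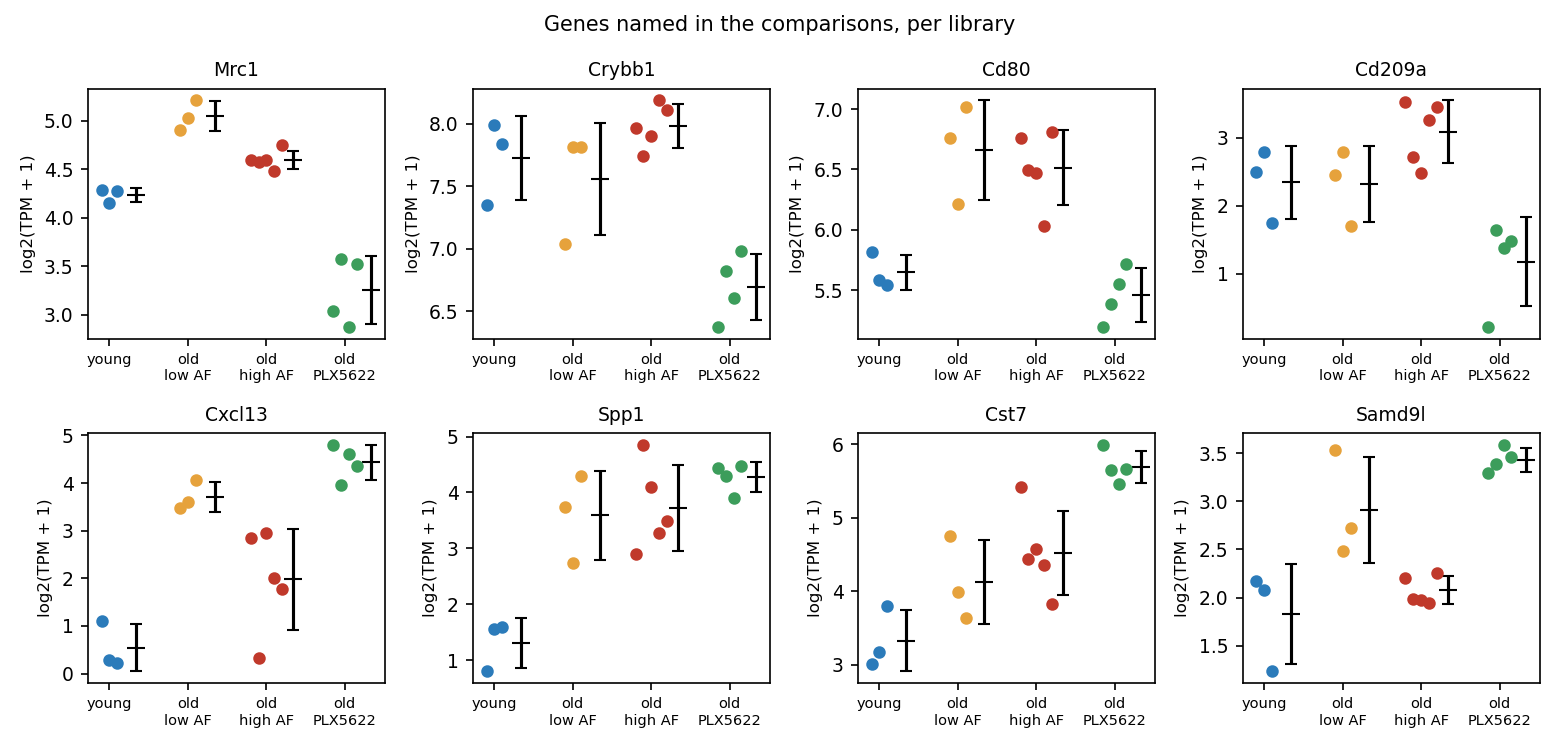
Levels of Mrc1, Crybb1, Cd80, Cd209a, Cxcl13, Spp1, Cst7 and Samd9l in each library (points). The mean ± SD per group is drawn on the scale marked on the axis. Groups are young (n = 3), AF-low (n = 3), AF-high (n = 5) and PLX5622 (n = 4). Averaged in TPM, Mrc1 is at 8.752 in PLX5622, 17.89 in young, 23.27 in AF-high and 32.2 in AF-low libraries.

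Border-associated macrophage markers fell as a list with PLX5622 (17 of 20 negative, median -0.67 against -0.02 for all genes, camera adjusted p = 1.64e-05; adjusted p = 0.286 with an estimated correlation). The scavenger receptor Stab1 was at 111.7 ± 10.5 against 184.1 ± 49.03 TPM in AF-high. Over all genes 2 of its members were lower, Mrc1 and Cd209a, and adjusted over the list alone 6. Mitochondrially encoded genes fell (13 of 13 negative, median -0.84, 3.93e-06), as did ribosomal protein genes (49 of 54, median -0.23, 8.82e-07), both with adjusted p = 0.675 with an estimated correlation. The same held for nuclear genes of the respiratory chain (41 of 55, median -0.19, 0.00296), inflammatory genes (29 of 39, median -0.23, 0.0129) and homeostatic genes (18 of 28, median -0.14, 0.0249). With an estimated correlation each of these 3 lists had adjusted p = 0.675 as well. The respiratory chain subunit Cox6b1 was at 53.38 ± 6.763 TPM in PLX5622 and 92.4 ± 20.9 in AF-high. The mitochondrial gene mt-Atp6 was at 678.1 ± 111.4 TPM in PLX5622, 2236 and 3597 in AF-high 2 and 3 and 802.9 to 1473 in the other AF-high libraries. With AF-high 2, AF-high 3 and AF-low 1 left aside the mitochondrial list had adjusted p = 0.0445. The endotoxin receptor Tlr4 was at 70.49 ± 5.784 TPM in PLX5622 and 113.5 ± 21.61 in AF-high. Cd80 (chromosome 16, 38455561 to 38496335) fell from 92.06 ± 18.62 to 43.48 ± 6.811 TPM (-1.05 ± 0.19, adjusted p = 0.0278). Adgrg1 fell from 342.9 ± 153.5 to 141 ± 11.71 (-1.18 ± 0.23, 0.0362) and Rpl38 from 261.8 ± 44.27 to 151.1 ± 28.3 (-0.79 ± 0.15, 0.0363). Csf1r, the receptor PLX5622 inhibits, was at 978.6 ± 60.65 and 1429 ± 266.8 TPM (-0.53 ± 0.13, 0.0763). Over all genes 2 homeostatic, 1 inflammatory and 1 ribosomal gene of these lists were lower, and 0 members of the respiratory or mitochondrial lists passed. Ndufv3, a respiratory chain gene that is not a member of the list, was among the genes called higher. When adjusted over the list alone, 9 mitochondrial, 9 ribosomal, 3 respiratory, 5 homeostatic and 9 inflammatory genes were lower and 2 inflammatory genes higher. The homeostatic call was lost without AF-high 2, 3 or 4 (adjusted p = 0.0501, 0.0562 and 0.0613), and the inflammatory and respiratory calls without AF-high 1 (0.166 and 0.128). Under quantile normalization the homeostatic and respiratory lists had adjusted p = 0.144 and 0.0822. The homeostatic list also had 0.0594 with a filter at 5 TPM, 0.123 with scaling that leaves aside the 50 highest genes and 0.15 without the 3 outlying old libraries.

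Altogether 83 genes were called between PLX5622 and AF-high, 21 higher and 62 lower, among 2019 at an unadjusted p under 0.05. Under quantile normalization the split was 35 and 36, and with scaling that leaves aside the 50 highest genes 25 and 25. The PLX5622 libraries held 10% ± 2.81 satellite-like transcripts against 0.858% ± 0.823 in the gated old libraries. The groups did not overlap for 863 genes (6.55%, against 1.59% by chance). Cd68 was at 931.7 ± 59.71 TPM in PLX5622 and 1287 ± 317.8 in AF-high (-0.44 ± 0.15, adjusted p = 0.184). Apoe, P2ry12 and Tmem119 had adjusted p = 0.665, 0.871 and 0.767. The count was 37, 205 and 31 without AF-high 2, 4 and 5, and 171 without AF-low 1. It was 31, 23 and 23 without young 1, 2 and 3, and 3, 1, 2 and 13 without PLX5622 library 1, 2, 3 and 4. Mrc1 was the 1 of 19 genes named by the rule that was called in all 15 fits that left 1 library out (highest adjusted p = 0.0411). Mrc1 lost this call in the fit with the replicate number as a block. Without AF-high 1, 2 or 5, AF-low 2 or 3, or any young or PLX5622 library, others had adjusted p from 0.0502 to 0.183.

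PLX5622 against AF-low microglia set the treated cells beside weakly autofluorescent cells of untreated mice. Border-associated macrophage markers fell as a list (19 of 20 negative, median log2 change -0.78 against -0.05 for all genes, camera adjusted p = 1.94e-08; adjusted p = 0.0581 with an estimated correlation). Mrc1 fell from 32.2 ± 3.602 TPM in AF-low (n = 3) to 8.752 ± 2.328 in PLX5622 (n = 4) (-1.79 ± 0.19, limma adjusted p = 0.00071). Cd163 (chromosome 6, 124304656 to 124330527) fell from 6.549 ± 0.5667 to 1.265 ± 0.8256 (-1.80 ± 0.27, 0.02) and F13a1 from 13.61 ± 4.716 to 4.541 ± 0.8261 (-1.35 ± 0.25, 0.047). These 3 were the members lower over all genes, and 9 were lower adjusted over the list alone. Emp3 fell from 289 ± 123.3 to 84.12 ± 8.59 TPM (-1.66 ± 0.30, 0.0423). Qtrt1, a transfer RNA-modifying enzyme, fell from 83.64 ± 35.2 to 27.9 ± 4.983 (-1.49 ± 0.25, 0.0409). Nearest on the higher side, not past the test, were Cst7, an inhibitor of lysosomal proteases, at 51.09 ± 8.278 TPM in PLX5622 and 17.47 ± 7.604 in AF-low (1.56 ± 0.33, 0.0858), Ly9 (0.85 ± 0.18, 0.0804) and Cebpzos (0.88 ± 0.19, 0.0858).

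Inflammatory genes fell as a list with PLX5622 (32 of 39 negative, median -0.30, adjusted p = 0.00591; adjusted p = 0.814 with an estimated correlation). Cd80 fell from 102.9 ± 27.91 TPM in AF-low to 43.48 ± 6.811 (log2 -1.20 ± 0.21, 0.0423), with Cxcl2 at 33.89 ± 8.546 in PLX5622 against 89.32 ± 21.32. Ribosomal protein genes fell (49 of 54 negative, median -0.25, 5.12e-05; adjusted p = 0.814 with an estimated correlation). Rps7 was at 157.2 ± 11.58 against 244.6 ± 17.98 TPM. Genes of disease-associated microglia rose as a list (22 of 30 positive, median 0.19, 0.00525; adjusted p = 0.814 with an estimated correlation). Lgals3 was at 8.838 ± 2.762 against 3.251 ± 0.8753 TPM and the receptor kinase Axl at 27.4 ± 7.174 against 14.27 ± 2.063. Over all genes 1 inflammatory gene (Cd80) was lower and 0 genes of the other 2 lists passed. When adjusted over the list alone, 4 inflammatory genes were lower, 0 ribosomal genes passed and 1 disease-associated gene was higher. The disease-associated call was lost without AF-low 1 or PLX5622 library 4 (adjusted p = 0.0534 and 0.0687), the inflammatory call without AF-low 3 (0.326) and the ribosomal call without AF-low 2 (0.0552).

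Of 13175 genes, 19 were called between PLX5622 and AF-low, 0 higher and 19 lower (limma), with 1880 at an unadjusted p under 0.05. The call with the smallest p after Mrc1, picked after its values were seen, was Cd74, from 135.9 ± 13.9 to 52.98 ± 7.426 TPM (log2 -1.35 ± 0.14, adjusted p = 0.00071). The groups did not overlap for 2132 genes (16.2%, against 5.71% by chance). Scaling that leaves aside the 50 highest genes moved the median of all genes by 0.134 and left 4 calls, median-of-ratios scaling left 6 and quantile normalization 4. Cd68, Apoe, P2ry12 and Tmem119 had adjusted p = 0.506, 0.814, 0.577 and 0.351. The count was 29 without AF-high 3, 9 and 7 without AF-high 4 and 5, and 4, 398 and 12 without AF-low 1, 2 and 3. It was 4 without each young library, and 2, 5, 3 and 7 without PLX5622 library 1, 2, 3 and 4. Of 6 calls named by the rule, Mrc1 was the 1 made in all 15 fits that left 1 library out (highest adjusted p = 0.00823). Cd74 was called in these 15 fits as well (highest adjusted p = 0.00972). In a fit of only both groups neither Mrc1 nor Cd74 was called (adjusted p = 0.0789 and 0.0688). Without AF-high 1, 4 or 5, AF-low 1 or 3, or any young or PLX5622 library, others had adjusted p from 0.0503 to 0.218.

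**Figure D3:**
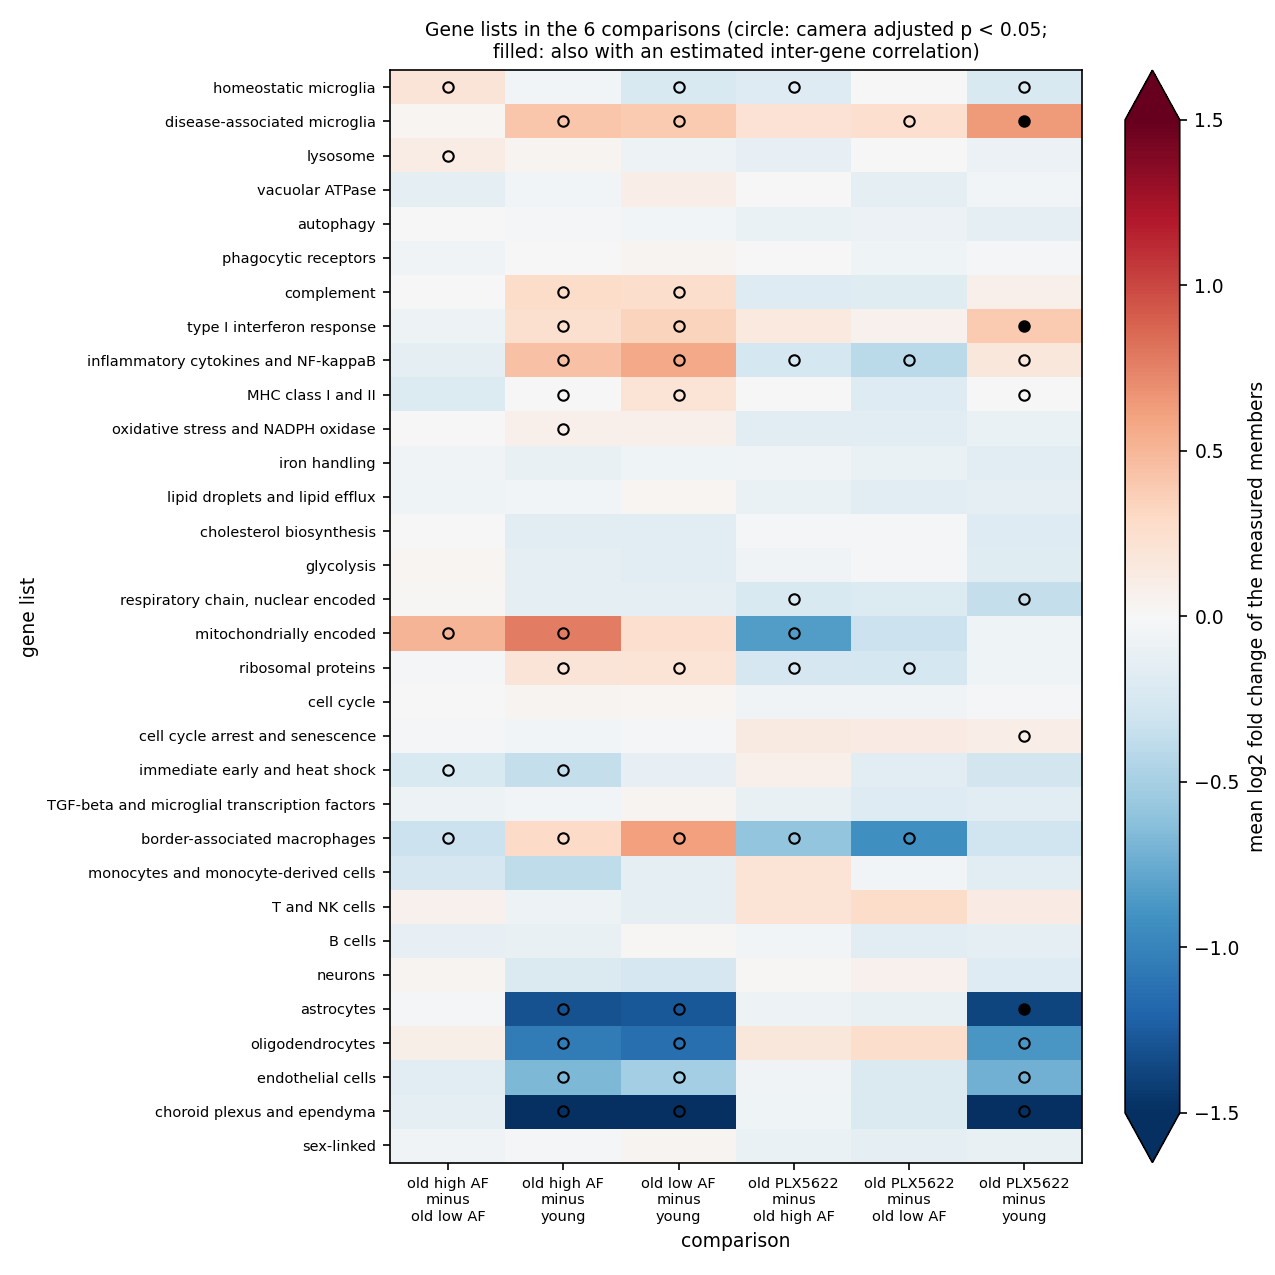
Mean log2 fold change of the measured members of each gene list (lines) in each of the 6 comparisons (columns), on a colour scale from -1.5 to 1.5. A circle marks camera adjusted p under 0.05 and a filled circle the 3 calls that also hold with an estimated correlation, all in PLX5622 against young.

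Between PLX5622 and young microglia, which differ in age and treatment, the largest rise was in Cxcl13, from 0.5156 ± 0.5567 TPM in young (n = 3) to 21.12 ± 5.345 in PLX5622 (n = 4) (log2 3.89 ± 0.49, limma adjusted p = 0.00609). Spp1 (chromosome 5, 104435118 to 104441050) rose from 1.558 ± 0.7083 to 18.55 ± 3.341 TPM (2.96 ± 0.43, 0.0125). Cst7 (chromosome 2, 150570415 to 150578944) rose from 9.313 ± 3.123 to 51.09 ± 8.278 (2.37 ± 0.33, 0.0104). Hcar2, a receptor for ketone bodies and niacin (chromosome 5, 123863570 to 123865499), rose from 3.07 ± 0.6798 to 12.59 ± 1.421 (1.75 ± 0.22, 0.00609). Sema6d, a semaphorin, fell from 10.64 ± 0.74 to 3.151 ± 0.5607 TPM (-1.495 ± 0.20, 0.00939) and S1pr1, a sphingosine-1-phosphate receptor, from 31.74 ± 0.9422 to 15.86 ± 1.419 (-0.96 ± 0.14, 0.0132). Ndrg2, abundant in astrocytes, fell from 27.4 ± 17.05 to 4.108 ± 0.9151 TPM (-2.21 ± 0.39, 0.046). Pltp, a lipid transfer protein listed here as endothelial, fell from 20.48 ± 12.03 to 3.578 ± 0.5114 (-2.03 ± 0.35, 0.0433). Ndrg2 was at 38.9, 35.5 and 7.814 TPM in young 1, 2 and 3 and Pltp at 23.3, 30.9 and 7.3, and their calls were lost in 14 and 12 of the 15 fits that left 1 library out (highest adjusted p = 0.368 and 0.307, both without young 2).

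Disease-associated microglial genes rose as a list with 24 of 30 members positive (median 0.32 against -0.12 for all genes, camera adjusted p = 1.25e-22), and type I interferon genes with 42 of 51 (median 0.37, 1.4e-17). Both held with an estimated correlation (adjusted p = 0.00182 each). In these lists 11 and 6 genes were higher adjusted over the list alone, and 2 and 2 over all genes. The latter were Cst7 and Spp1, and Ifi204, an interferon-induced DNA sensor, from 25.78 ± 6.673 to 55.81 ± 8.706 TPM (log2 1.10 ± 0.17, adjusted p = 0.0195), with Samd9l, from 2.697 ± 1.176 to 9.82 ± 0.9434 (1.60 ± 0.27, 0.0361). Inflammatory genes rose (25 of 39, median 0.17, 1.46e-06; adjusted p = 0.183 with an estimated correlation), with Tnf at 330 ± 53.11 against 189.1 ± 5.783 TPM. The MHC list was called higher (0.00889; adjusted p = 0.165 with an estimated correlation) with 13 members positive and 13 negative, a median of -0.003 and a mean of 0.006. B2m was at 8461 ± 705.6 against 5894 ± 149.1 TPM. The senescence list was called higher (0.0214; adjusted p = 0.207 with an estimated correlation) with a median of -0.02 and a mean of 0.10. Lmnb1, a lamin that declines in senescent cells, was at 11.77 ± 1.208 TPM in PLX5622 and 4.956 ± 0.5334 in young. Homeostatic genes fell (24 of 28 negative, median -0.21, 0.00107; adjusted p = 0.378 with an estimated correlation), with Fcrls at 581.5 ± 29.44 against 916.5 ± 52.85 TPM. So did nuclear respiratory chain genes (52 of 55, median -0.28, 5.27e-07; adjusted p = 0.262 with an estimated correlation), with Sdhc at 28.61 ± 5.921 against 47.33 ± 3.975. With values adjusted over the list alone, 2 MHC genes were higher, 2 homeostatic genes were lower, and the inflammatory, senescence and respiratory lists had 0. None of these 5 lists held a gene called over all genes (0). The senescence call was lost without young 1 or PLX5622 library 4 (0.0539 and 0.122). With young 1 and 2 left aside the MHC, respiratory and senescence lists had adjusted p = 0.121, 0.384 and 0.0815. The MHC list had 0.0602 under quantile normalization and the senescence list 0.0596 with a filter at 5 TPM and 0.0505 with array weights.

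Border-associated macrophage markers were not called between PLX5622 and young (14 of 20 negative, median -0.21, adjusted p = 0.109; adjusted p = 0.437 with an estimated correlation). Astrocyte markers fell from young to PLX5622 (10 of 10 negative, median -0.75, adjusted p = 5.41e-10), also with an estimated correlation (adjusted p = 0.0242). Oligodendrocyte (8 of 10, -0.46, 0.00158; adjusted p = 0.183 with an estimated correlation), endothelial (11 of 11, -0.63, 0.000427; adjusted p = 0.183 with an estimated correlation) and choroid plexus markers (5 of 6, -2.13, 0.00037; adjusted p = 0.165 with an estimated correlation) fell too. Members lower adjusted over the list alone were 7, 1, 2 and 4, and over all genes only Pltp (1). Kl, a choroid plexus gene, was at 38.6, 27.7 and 2.35 TPM in young 1, 2 and 3 and at 2.099 ± 0.2804 in PLX5622. With young 1 and 2 left aside the astrocyte list was still called lower (adjusted p = 0.0198, with 1 young library), while the oligodendrocyte, endothelial and choroid plexus lists changed direction and were not called (adjusted p = 0.826, 0.996 and 0.544). With only both groups the oligodendrocyte and choroid plexus lists had adjusted p = 0.061 and 0.0974, and with array weights the choroid plexus list had 0.0537.

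Between PLX5622 and young 12 genes were called, 8 higher and 4 lower, with 689 at an unadjusted p under 0.05. The median of all genes was -0.12, and median-of-ratios scaling and quantile normalization moved it by 0.107 and 0.117. The split was 14 and 3 under median-of-ratios scaling, 17 and 5 under quantile normalization and 14 and 4 with scaling that leaves aside the 50 highest genes. The groups did not overlap for 2106 genes (16%, against 5.71% by chance). Cd68 was at 931.7 ± 59.71 TPM in PLX5622 and 899.3 ± 45.82 in young (adjusted p = 0.992). Apoe, P2ry12 and Tmem119 each had adjusted p = 0.979. Even so, Apoe ran from 487.9 to 826.9 TPM in PLX5622 and 348.3 to 452.6 in young, without overlap. P2ry12 ran from 1785 to 2164 and 2265 to 2718 TPM, also without overlap, while Tmem119 overlapped. The fit shares the spread between all groups. Within-group SDs were 0.295 in PLX5622, 0.304 in young, 0.535 in AF-low and 0.532 in AF-high. A high adjusted p here thus does not show that a gene was unchanged. The count was 5, 1 and 53 without young 1, 2 and 3 and 2, 7, 5 and 5 without PLX5622 library 1, 2, 3 and 4, and 0 with young 1 and 2 left aside (Cxcl13 and Hcar2 adjusted p = 0.462). Of 10 named calls, Hcar2 was the 1 made in all 15 fits that left 1 library out (highest adjusted p = 0.0454). Others had adjusted p from 0.05 to 0.368, and each of the 15 libraries ended at least 1 call when left out. Cxcl13 lost its call without young 2 (0.0717).

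**Figure D4:**
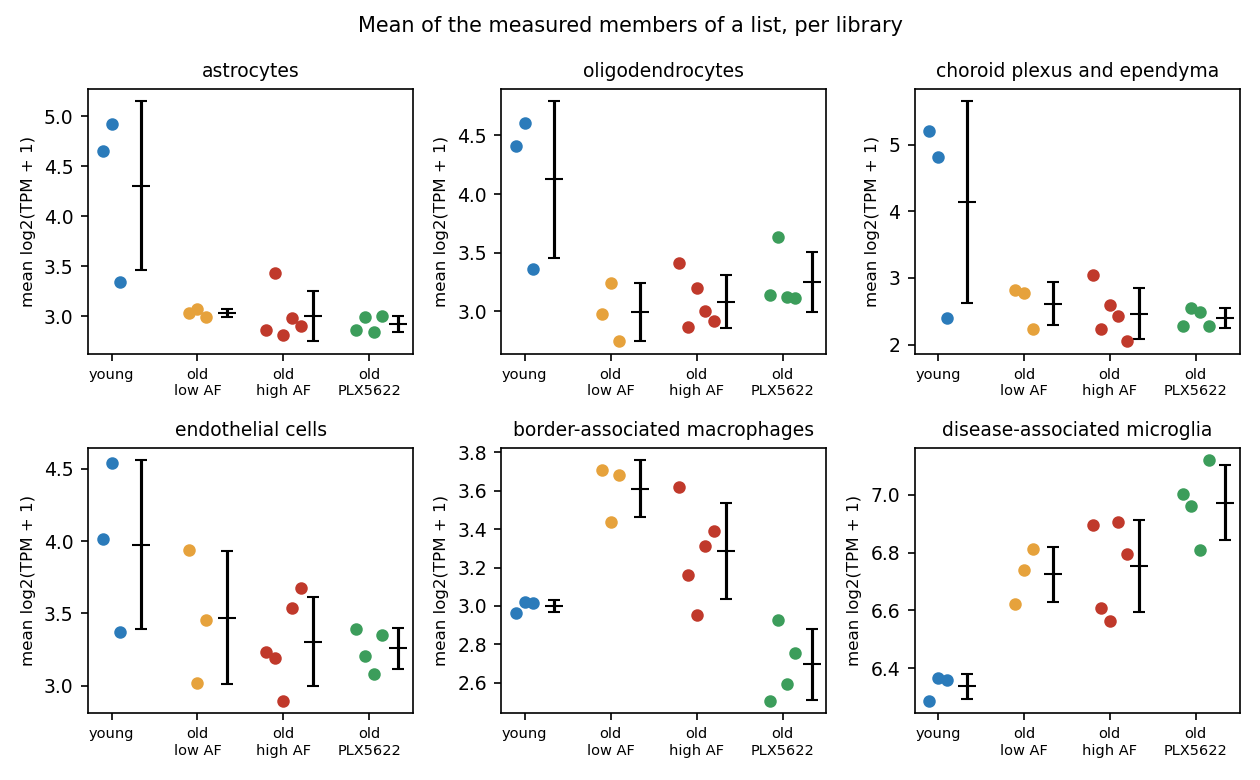
Mean log2(TPM + 1) over the measured members of 6 gene lists in each library (points), with mean ± SD per group. Young 1 and 2 stand above the other libraries for the choroid plexus list, and the PLX5622 libraries lie lowest for the border-associated macrophage list.

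Fold changes were also compared between comparisons, across 13175 genes, which are not independent replicates. The AF-high against young difference and the PLX5622 against AF-high difference had a correlation of -0.674, where simulated groups without effects that share the 5 AF-high libraries gave -0.685. Their covariance was -0.109 against a simulated -0.0568, a difference of -0.0522, and with the AF-high libraries split between the comparisons the correlation was -0.242 (range -0.303 to -0.177 over 20 arrangements). The gate difference and the PLX5622 against AF-high difference had a correlation of -0.315 (simulated -0.52), a covariance of -0.0465 against -0.0567, and a split correlation of 0.044 (range -0.064 to 0.163). The AF-low against young difference and the gate difference had a correlation of -0.56 (simulated -0.687) and a covariance of -0.0944 against -0.0949. That difference of 0.000541 lies within the SD of the simulations (0.00325), so shared libraries without effects gave a covariance of this size. The 3 shared AF-low libraries cannot be split with at least 2 on each side.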

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

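Of the tests reported in this part, those of age by itself, of RNA of other brain cells in young 1 and 2, of an age difference shared by the 3 young libraries and of scaling by a few abundant genes were chosen after the results were seen.

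The first pattern is the larger spread among AF-high and AF-low libraries. The ratio of within-group SDs, gated old over the other groups, was 1.59 for genes below 5 TPM and 1.75 for genes of at least 100 TPM. With a library left out the latter was 1.67 at the lowest. The SD itself in the gated groups was 0.578 log2 units below 5 TPM and 0.435 at 100 TPM or more. Fewer sampled transcripts in the gated libraries could raise the SD by a like factor at every level. The ratio therefore cannot decide whether sampling of few transcripts is a cause, which stays open. Age by itself cannot be told apart from gate and treatment: the PLX5622 libraries, of the same age, had a spread 0.972 times that of young libraries, but they differ from the gated groups in treatment and perhaps in gate. Small or uneven cell numbers per sort and differences between old animals stay open as hypotheses, and neither was tested. AF-high 2, AF-high 3 and AF-low 1 had the lowest array weights (0.313, 0.373 and 0.399).

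The next pattern is the high level of astrocyte, oligodendrocyte, endothelial and choroid plexus markers in young libraries. RNA of other brain cells in young 1 and 2 stays open as a candidate explanation: the most abundant markers stood far apart between the young libraries (Ttr 7770, 5084 and 175.7 TPM, Enpp2 909, 632 and 23.9 TPM in young 1, 2 and 3), and of the 12 calls of these 4 lists in comparisons with young, 1 was still made with young 1 and 2 left aside, astrocyte markers against PLX5622 (adjusted p = 0.0198), which that RNA alone would not give but which rests on 1 young library. An age difference shared by the 3 young libraries stays open, since 4 members had every young library above every old library, while 18 had young 1 and 2 above all 13 others and young 3 lay above the median of the old libraries in 27. Of the 37 members 2 are in another list (Trf and Slc2a1) and 12 were at 5 TPM or more in every library, so microglia may express some of them. A sort on microglial surface markers that excludes astrocyte and endothelial antigens, or fresh libraries from young mice, would separate these explanations.

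The last pattern is the low level of border-associated macrophage markers with PLX5622 against both gated old groups, in which the list was also higher than in young; against young it was not called (14 of 20 negative, adjusted p = 0.109). Scaling by a few abundant genes, such as the satellite-like transcripts, could not be judged by the list test. Over 3 other scalings and both comparisons with gated old cells the list's highest camera adjusted p was 1.4e-05. Camera compares a list with all other genes, so a scaling that moves all genes of a library alike could hardly change it. The values show only that the list fell relative to other genes under each scaling. Fewer border-associated macrophages in the sort is a candidate explanation, since members deviated together within groups with a mean correlation of 0.0917 (random median 0.0078, 95th percentile 0.0616), but a programme shared by microglia would covary as well. Of the 20 measured members 3 are in another list (Cd163, Stab1 and Cp) and 8 were at 5 TPM or more in every old library; among the most abundant, Stab1 was at 111.7 ± 10.5 TPM in PLX5622 and 184.1 ± 49.03 in AF-high and Dab2 at 43.14 ± 8.795 and 107.3 ± 51.15. A gate on CD206, the product of Mrc1, would remove these macrophages, and a change of the microglia themselves stays open.

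Other groupings of the same libraries show how far chance can be excluded. Few splits gave as many called genes as the real one between PLX5622 and AF-low (19, at most 1 in the other splits, as many in 1 of 35). The same held between PLX5622 and young (12, at most 1, as many in 1 of 35), and 1 of 35 is the smallest share possible there. For PLX5622 against AF-high, 2 of 100 drawn splits, the real one included, gave as many genes (83). The other was AF-high 1, 2, 3 and 5 against AF-high 4 with the PLX5622 libraries. These shares were not adjusted over the comparisons tested, so they make chance less likely but do not exclude it. Chance cannot be excluded for the genes at an unadjusted p under 0.05 between AF-high and AF-low (1082, up to 2288 in other splits, as many in 43 of 56) or between AF-high and young (1446, up to 1975, as many in 6 of 56). For the lists it cannot be excluded between AF-high and AF-low (5, up to 9, 17 of 56), AF-high and young (14, up to 14, 3 of 56), PLX5622 and AF-high (6, up to 10, 17 of 100), PLX5622 and AF-low (4, up to 6, 14 of 35) or PLX5622 and young (11, up to 15, 10 of 35). For AF-low against young the 10 splits are too few: 6 genes were called with at most 1 in other splits, and 12 lists with at most 11, the real split being the 1 with as many. These splits do not cover unequal spread between the groups: simulated libraries with the SD measured per gene and group gave 44 false calls of 142 for PLX5622 against AF-low, 3 of 93 for PLX5622 against young and 16 of 111 for PLX5622 against AF-high, so false calls of that kind stay open. The highest of the 56 splits of the gated libraries, AF-high 1, 2 and 5 with AF-low 1 and 3 against the others, called 306 genes where the gates called 0 and the median of the other splits was 0. A structure of the samples that does not follow the gate is a hypothesis from that split, not tested against the highest count expected without one.

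In 20 of 374 tested groups of 4 or 5 libraries (5.35%), 1 library stood far from the rest, about the 1 in 20 that chance gives. The values are the gap to the nearest library as a share of the group's range. In AF-high, AF-high 2 was highest for Ece1 (0.805), Lgals3bp (0.796), Stab1 (0.749) and the astrocyte list mean (0.723) and lowest for Ctso (0.886) and Ripk3 (0.749). AF-high 1 was highest for Apod (0.836) and lowest for the homeostatic list mean (0.743), AF-high 3 highest for Prlr (0.781) and lowest for Ndufv3 (0.807), AF-high 4 lowest for Adgre5 (0.789) and AF-high 5 lowest for Enpp2 (0.735). In PLX5622, library 4 was highest for Ctsd (0.977), Sdhc (0.956), Atp5d (0.87) and Mospd3 (0.848), library 2 for the oligodendrocyte list mean (0.948) and Enpp2 (0.902), and library 3 for the share of TPM in the 50 highest genes (0.943, at 31.12%), while library 3 was lowest for Golm1 (0.939).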

How the results depend on the processing

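Leaving aside 3 outlying old libraries (AF-high 2 and 3, AF-low 1), leaving aside young 1 and 2, and weights by group are tests chosen after seeing the data; the others were fixed in advance. Unless a reason is given, the cause of a change was not tested. Pseudocounts of 0.1 and 5, no filter and a filter at 5 TPM left every count of called genes within 1.5 times. The count-based test was not run, since the table holds no counts, and depth, being unknown, limits every low value.

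Genes called between AF-high and young (0) became 6 with median-of-ratios scaling, 1 with quantile normalization, 129 with array weights and 13 with weights by group. For AF-low against young the 6 became 12 with median-of-ratios scaling, 11 with quantile normalization, 0 with only the libraries of both groups, 44 with array weights, 1 without the 3 outlying libraries and 0 without young 1 and 2. For PLX5622 against AF-high the 83 became 50 with scaling that leaves aside the 50 highest genes, 7 with only both groups, 441 with array weights, 286 without the 3 outlying libraries, 3 without young 1 and 2 and 180 with weights by group. For PLX5622 against AF-low the 19 became 6 with median-of-ratios scaling, 4 with quantile normalization, 4 leaving aside the 50 highest genes, 0 with only both groups, 89 with array weights, 45 without the 3 outlying libraries and 3 without young 1 and 2. For PLX5622 against young the 12 became 22 with quantile normalization, 59 with only both groups, 420 with array weights, 30 without the 3 outlying libraries, 0 without young 1 and 2 and 241 with weights by group. Fits of fewer libraries have fewer residual degrees of freedom by construction. Leaving out each library in turn gave 0 to 1 genes for AF-high against AF-low, 0 to 60 for AF-high against young, 0 to 182 for AF-low against young, 1 to 205 for PLX5622 against AF-high, 2 to 398 for PLX5622 against AF-low and 1 to 53 for PLX5622 against young.

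No pairing of libraries by replicate number was seen: no pair of groups had every same-numbered correlation of deviations above 0.1 (lowest -0.0812, highest 0.141). For AF-high and AF-low the 3 same-numbered pairs ran from -0.0812 to 0.053, too few to exclude a pairing by animal. With the number as a replicate block, 0 genes were called for AF-low against young and 0 for PLX5622 against AF-high (Mrc1 adjusted p = 0.0751). There were 3 for PLX5622 against AF-low and 3 for PLX5622 against young, and the count of 0 in the other comparisons was unaltered. The block ended the calls of 35 gene results named by the rule and 3 list results. These lists were MHC (camera adjusted p = 0.0734) and oxidative stress (0.242) in AF-high against young, and senescence (0.19) in PLX5622 against young.

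With an estimated correlation the lists called were 0 for AF-high against AF-low, 0 for AF-high against young, 0 for AF-low against young, 0 for PLX5622 against AF-high, 0 for PLX5622 against AF-low and 3 for PLX5622 against young; with fry they were 0, 2, 6, 1, 1 and 3 in that order. AF-high against young had 9 lists with a filter at 5 TPM, which leaves fewer members to test, and PLX5622 against AF-high had 10 with array weights. Leaving out single libraries gave 3 to 7 lists (3 without AF-high 5 or AF-low 1), 10 to 16, 9 to 14, 5 to 9, 3 to 4 and 11 to 13. With young 1 and 2 left aside 7 list results reversed: endothelial (adjusted p = 0.727) and choroid plexus (0.727) in AF-high against young, endothelial (1) and choroid plexus (0.553) in AF-low against young, and oligodendrocytes (0.826), endothelial (0.996) and choroid plexus (0.544) in PLX5622 against young. No list called lost its call under either pseudocount, median-of-ratios scaling or no filter (52 results); 5 did under quantile normalization and 1 with scaling that leaves aside the 50 highest genes. Of 265 gene results named by the rule 6 lost their call and 8 gained one under median-of-ratios scaling, and 8 and 5 under quantile normalization. Of the other gene results, named after their values were seen, 0 reversed; the calls of Spi1 against AF-high and AF-low were lost under quantile normalization (adjusted p = 0.079 and 0.0937), with scaling that leaves aside the 50 highest genes (0.0552 and 0.0754), with only both groups (0.0896 and 0.0789) and without young 1 and 2 (0.102 and 0.122), and that against AF-low without the 3 outlying libraries (0.0678). Slc11a2 lost its call with only both groups (0.059) and without young 1 and 2 (0.0622). Lilrb4a and Ptger4 lost theirs with only both groups (0.248 each), without the 3 outlying libraries (0.0616 and 0.0998) and without young 1 and 2 (0.997 and 0.715). Ptger4 did so too with a pseudocount of 0.1 or no filter (0.0523 each), leaving aside the 50 highest genes (0.0623) and weights by group (0.0711). Clec7a gained a call with a filter at 5 TPM (0.0465), quantile normalization (0.0445), array weights (0.0135) and weights by group (0.0227). Lilrb4a, Ptger4, Spi1 and Slc11a2 lost their calls with the replicate block (0.0927 to 0.166).

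With the shared AF-high libraries split, the correlation of the AF-high against young and PLX5622 effects was -0.242 and that of the gate and PLX5622 effects 0.044, with a range from -0.064 to 0.163 over 20 arrangements that spans 0; over the 6 genes called between AF-low and young, that of the AF-low against young and gate effects was -0.821, but these genes were selected for being high in AF-low, the group both comparisons share, which by itself gives a negative value, so it says nothing of a relation. The first 2 relations have no value over called genes, since 0 were called. Leaving out single libraries gave -0.724 to -0.612, -0.413 to -0.137 and -0.74 to -0.485.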

Other observations

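The tests in this part were planned; the 3 genes of the next paragraph were picked for mention after their values were seen, from lists fixed before.

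Among transcription factors of microglia, Spi1, the gene of the myeloid master regulator PU.1, stood at 396.7 ± 24.3 TPM in young (n = 3), 698.8 ± 113.9 in AF-low (n = 3), 603.6 ± 85.17 in AF-high (n = 5) and 387.9 ± 35.97 in PLX5622 (n = 4). It fell with PLX5622 against AF-high (log2 -0.63 ± 0.13, limma adjusted p = 0.0411) and against AF-low (-0.84 ± 0.15, 0.0423). The first call was lost without AF-high 2 or 5, AF-low 3, or any young or PLX5622 library (highest adjusted p = 0.178). The other was lost without AF-high 4, AF-low 1 or 3, or any young or PLX5622 library (highest 0.185). Slc11a2, an iron transporter of endosomes, fell from 116.1 ± 19.12 TPM in AF-high to 57.03 ± 7.624 in PLX5622 (-1.01 ± 0.17, 0.0231), a call lost without any 1 of the PLX5622 libraries (adjusted p from 0.0539 to 0.105). Clec7a, a phagocytic receptor for fungal glucans and a marker of activated microglia, was at 41.7 ± 2.488 TPM in PLX5622 and 17.96 ± 10.56 in AF-high (1.32 ± 0.30, 0.0549 over all genes and 0.0107 among phagocytic receptors, adjusted over the list alone). Over all genes it was called without AF-high 4 (0.0111) or AF-low 1 (0.0423).

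Of the 32 tested lists, 14 were called in no comparison. Their smallest camera adjusted p over the 6 comparisons was 0.295 for the vacuolar ATPase that acidifies lysosomes, 0.548 for autophagy, 0.359 for phagocytic receptors, 0.44 for iron handling, 0.282 for lipid droplets and lipid efflux, 0.388 for cholesterol biosynthesis, 0.393 for glycolysis, 0.112 for the cell cycle, 0.112 for TGF-beta and microglial transcription factors, 0.0911 for monocytes, 0.112 for T and NK cells, 0.524 for B cells, 0.216 for neurons and 0.506 for sex-linked genes.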
